A study of Mus musculus with 4 samples.

How the data were processed

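Gene expression was measured in mouse bone marrow-derived macrophages on 4 Agilent arrays with 2 colours each. Per the labels, bone marrow cells of male mice, 6 weeks old, were grown for 7 days with the growth factor GM-CSF at 25 ng/ml. The LPS samples received bacterial lipopolysaccharide at 100 ng/ml for 6 h, and 10 µg of total RNA went into each labelling. Every array held wildtype RNA in the Cy3 channel and Cdk5r1 knockout RNA in the Cy5 channel. There were 2 basal and 2 LPS arrays, called biological replicates in the labels. The dyes were not swapped on any array, so a dye effect of a probe cannot be told from the genotype in a knockout to wildtype ratio. Such an effect cancels in the difference of ratios between conditions and in LPS against basal within a channel. This holds as long as it is constant and the probe has signal in both conditions. All 4 arrays came from 1 slide and 1 scan, per the file headers, so no batch term could be fitted.

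The deposited scanner files hold the intensity of each spot in both channels, with local background intensities and quality flags. They were made with Agilent Feature Extraction, version 11.5.1.1 per the file headers and version 9.3.2.1 per the submitters' processing notes. The files give median foreground intensities, and these were used where the design had assumed mean intensities. The deposited log10 ratios of the spots, red over green, were 0 for 13.4% to 16.4% of the spots of an array and were not used further. The authors' value table holds log2 ratios of knockout over wildtype: its columns differ from the log2 ratio of the processed signals by a constant between -0.0020 and 0.0051, within a tolerance of 0.001 for 100% of the probes with a single spot. Its column medians were 0.016, 0.034, 0.029 and 0.031. How the constant was chosen is not given in the sources used here.

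Each array carried 44397 spots, of which 1377 were controls and 43020 were probe spots for 39429 probes. Of these probes, 399 were spotted 10 times and were averaged. Between 207 and 255 probe spots per array carried an outlier flag and were left out, which removed 63 probes. No probe spot was saturated. The share of probe spots well above background was 68.3% to 71.0% in Cy3 and 62.1% to 65.0% in Cy5. The number of arrays limits the precision of every value.

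Background was corrected with normexp (offset 50), ratios were normalised by loess within each array with control and outlier spots at weight 0, and levels were set across arrays by Aquantile, all in limma 3.58.1 under R 4.3.3. Probes were kept when at least 1 channel was well above background on 2 or more of the 4 arrays, which left 28635 probes. The files pair probes with accessions and not with symbols. Accessions were matched without their versions to a RefSeq gene table of assembly GRCm38.p6, while the file headers name mm9 as the array's build, so no coordinates are given. Of the 39429 probes, 27508 matched a symbol and 11921 kept the accession of the file. The brightest kept probe stood for each gene, giving 23570 genes or accessions, 15986 of them with a symbol. Il12b was to be named but was not matched through this table and is not reported.

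The 6 comparisons were fitted in limma with eBayes, each with Benjamini-Hochberg adjustment over all 23570 genes and a threshold of 0.05. They were knockout against wildtype under basal conditions, under LPS and averaged over both, the difference of the knockout effect between the conditions, and LPS against basal in each genotype. All p-values are two-sided, and every adjusted p below comes from limma. Standard errors (SE) are those of the moderated fit, and n = 2 arrays per condition. A group in which a probe was not well above background on any array has only a bound. The fold is then given as "at least", from the bright group's mean against the higher of the lowest well-above-background signal and the probe's own, per channel, and stays open to dye bias.

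There were 32 gene lists, fixed before the data were examined and tested with camera at a preset correlation of 0.01. With a correlation estimated from the residuals, no list passed in any of the 6 comparisons. That form of camera rests on the few residual degrees of freedom left by 4 arrays, so it has little power. For the basal interferon list the estimated correlation of 0.0018 was below the preset one, yet the unadjusted camera p went from 3.27e-17 to 0.0108. A list that did not pass with it is therefore not shown to be unchanged. Other lists had estimated correlations well above the preset one. For the cell cycle list it was 0.371 in knockout against wildtype, and 0.608 and 0.788 for LPS in wildtype and knockout cells. For the interferon list it was 0.487 and 0.496 for LPS in wildtype and knockout cells. Where such a correlation holds, the p at the preset correlation is too low. fry was run beside camera and asks whether a list moves on balance, without setting it against other genes. Named genes follow a rule fixed beforehand. It takes Cdk5r1, Cdk5, Il10, Tnf, Il6 and Il1b in every comparison, and the 10 largest rises and falls past the threshold that go the same way on every array involved. It adds up to 4 members per list with the smallest p, and the 5 genes with the smallest p in a direction where fewer than 5 passed. Gene models without an ordinary symbol were passed over. Members of near-identical families, among them Slfn, Oas, Ifit, Csta, Olfr, Serpina3, H2 and Hbb genes, are uncertain, since a probe may bind several copies.

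The fits were tested on simulated data for 23570 genes with 200 changed genes. The spread of each gene was drawn at random from the distribution fitted to the real values, with independent noise and no dye effect. Measured levels entered only for LPS against basal. At a log2 change of 1 the fit recovered 97.0% of the changed genes for knockout against wildtype under basal conditions and 97.0% under LPS. It recovered 77.6% for the difference of the knockout effect, 13.4% for the LPS response of wildtype cells and 0% for that of knockout cells. At a log2 change of 2 these shares were 100%, 100%, 100%, 81.8% and 78.8%. For the average over both conditions they were 100% at either size. The adjustment is stricter when fewer genes change, and 9851 and 9853 genes passed for LPS in wildtype and knockout cells. The LPS shares simulated with 200 changed genes are therefore not those of the real LPS fits. The same holds for knockout against wildtype, where 1147 genes passed under basal conditions, 2922 under LPS and 4281 averaged over both. Alternatives covered the background correction, both normalisation steps, the deposited value table, the filter, the choice of probe, the spread model, a replicate block, each array left out in turn, single-condition fits and a separate channel model. Median centring replaces loess with 1 shift per array, so it does not remove a trend of the ratio with intensity. The median log2 ratio of the kept genes was then 0.087 basal and 0.072 under LPS, against 0.0024 and -0.00075 in the main fit.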

Results

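The series compared macrophages of wildtype mice with macrophages of Cdk5r1 knockout mice, a gene that encodes p35, an activator of the kinase CDK5. The question was how the knockout changes gene expression at rest and after LPS, a bacterial cell wall component that activates macrophages. There were 2 arrays per condition, each setting knockout RNA against wildtype RNA. Median foreground intensities of the arrays were 76.0 to 97.5 in Cy3 and 116 to 145.5 in Cy5, over median backgrounds of 25.0 to 27.0 and 46.0 to 48.0. Across genes, log2 ratios correlated at r = 0.61 between the basal arrays and r = 0.78 between the LPS arrays. Between a basal and an LPS array r was 0.47 to 0.64, so the basal arrays were not more alike than some arrays of different conditions. Genes are not independent replicates. The labels call the arrays biological replicates without naming the animals.

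Cdk5r1 was lower in the knockout channel on all 4 arrays. Its log2 ratio was -0.37 and -0.59 on the basal arrays and -2.55 and -2.29 on the LPS arrays. Its second probe gave means of -0.49 ± 0.029 (SD, n = 2) under basal conditions and -2.01 ± 0.0205 (SD, n = 2) under LPS. Both probes were well above background in both channels of every array, so the knockout channel kept signal. Whether either probe lies in the deleted part of the gene is not known here. LPS raised Cdk5r1 in wildtype cells by 1.97 ± 0.21 (log2, SE, n = 2, limma adjusted p = 0.0032), while the change in knockout cells was 0.03 ± 0.29 (adjusted p = 0.95). Cdk5 itself had a log2 ratio of 0.06 ± 0.068 under basal conditions and 0.05 ± 0.068 under LPS (adjusted p = 0.67 and 0.65). The Y-linked gene Ddx3y had mean log2 ratios of 0.09 and 0.07, and Eif2s3y 0.13 and 0.12, in basal and LPS arrays. Both Xist probes were not well above background on any array.

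**Figure D1:**
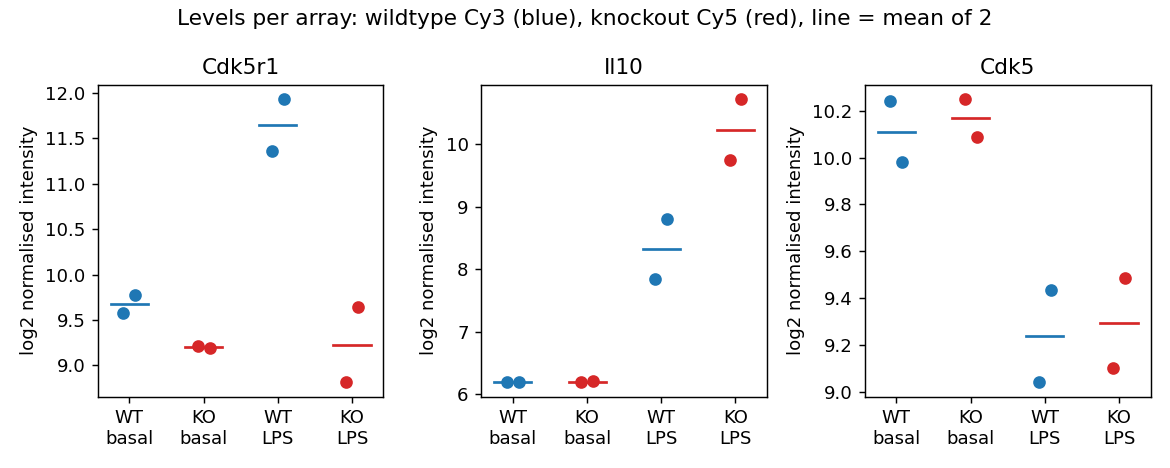
Log2 normalised intensity of Cdk5r1, Il10 and Cdk5 on every array, wildtype Cy3 in blue and knockout Cy5 in red, with points for 2 arrays per group and a line at their mean. Mean Cdk5r1 under LPS was 11.64 in wildtype and 9.23 in knockout, and mean Il10 was 8.33 and 10.23.

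LPS against basal in wildtype cells asked which genes the stimulus changed. The largest rise was that of the cytokine gene Il6, by 10.31 ± 0.15 (log2, SE, n = 2, limma adjusted p = 0.00019), followed by the antiviral gene Rsad2 (8.94 ± 0.28) and the chemokine gene Cxcl10 (8.86 ± 0.14). Il1b rose by 8.58 ± 0.23, Acod1, which makes itaconate, by 8.07 ± 0.13, and the prostaglandin synthase gene Ptgs2 by 7.98 ± 0.089. Tnf rose by 5.12 ± 0.37. Il10 rose at least 4.40-fold from a basal level not well above background. The receptor genes Vipr1 and Gpr146 fell by 5.64 ± 0.17 (-1.69 by the other kept probe of Vipr1) and 5.17 ± 0.31, Rab3il1 fell by 5.41 ± 0.15, and the transcription factor gene Cebpa fell by 4.13 ± 0.19.

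By group, all 38 measured interferon-stimulated genes rose in wildtype cells, among them Ifit1 (8.09 ± 0.20) and Oasl1 (8.44 ± 0.29), with camera adjusted p = 3.11e-22 and 0.52 with an estimated correlation. All 22 genes of NF-kappaB signalling and its feedback rose, with Tnfaip3 at 4.51 ± 0.13 and Traf1 at 4.05 ± 0.096 (camera adjusted p = 6.07e-14, and adjusted p = 0.25 with an estimated correlation). All 20 pro-inflammatory cytokine genes rose (adjusted p = 4.11e-12, and adjusted p = 0.25 with an estimated correlation). Of 21 chemokine genes 19 rose and 0 fell, with Cxcl9 at 6.86 ± 0.13, and 4.85 by its other kept probe (adjusted p = 4.62e-09, and adjusted p = 0.25 with an estimated correlation). Of 36 cell cycle genes 29 fell and 2 rose, with Kif23 at -2.41 ± 0.13 and Mcm3 at -2.10 ± 0.17 (adjusted p = 8.56e-08, and adjusted p = 0.56 with an estimated correlation). Of 23 lysosome genes 16 fell and 0 rose, with Npc1 at -1.29 ± 0.12 (adjusted p = 0.00029, and adjusted p = 0.53 with an estimated correlation). Dendritic cell markers moved both ways, 11 up and 5 down, with Zbtb46 at 5.38 ± 0.17, but 1.06 by its other kept probe, and Ccr7 at 3.41 ± 0.095 (adjusted p = 0.011, and adjusted p = 0.48 with an estimated correlation). Adjusted over the list alone, the counts were the same for the interferon, NF-kappaB, cytokine and chemokine lists, and 30 cell cycle and 17 lysosome genes fell.

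In total 4304 genes rose and 5547 fell in wildtype cells. Scaling each channel to its 75th percentile gave 11478 rises and 4210 falls, with the median of all genes at 0.38, so small changes depend on how levels are set across arrays. Without basal replicate 1 the total went from 9851 to 5548, and without basal replicate 2 to 5194.

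LPS against basal in knockout cells asked the same of the knockout. Il6 rose by 10.02 ± 0.13 (log2, SE, n = 2, limma adjusted p = 0.00032), Oasl1 by 9.50 ± 0.29, Rsad2 by 9.35 ± 0.38, Cxcl10 by 9.02 ± 0.22 and Il1b by 8.02 ± 0.28. Il10 rose at least 16.4-fold from a basal level not well above background, and Tnf rose by 4.86 ± 0.32. Rab3il1 fell by 5.70 ± 0.18, Vipr1 by 5.55 ± 0.24 (-1.79 by its other kept probe), and the chemokine receptor gene Ccr6 by 5.04 ± 0.19. All 38 interferon-stimulated genes rose (camera adjusted p = 1.63e-22, and adjusted p = 0.48 with an estimated correlation). Of the cytokine genes 19 of 20 rose, and 20 adjusted over the list alone (adjusted p = 5.33e-11, and adjusted p = 0.25 with an estimated correlation). Of the cell cycle genes 30 of 36 fell and 2 rose (adjusted p = 2.16e-07, and adjusted p = 0.51 with an estimated correlation). In total 4481 genes rose and 5372 fell. Of these, 3786 rises and 4716 falls were shared with wildtype cells, where independent lists would share 818 and 1260, and 2 genes passed in opposite directions. Both responses were read on the same arrays, so part of the overlap may come from shared spots and scans. Scaling to the 75th percentile gave 10823 rises and 4164 falls, and the total was 4794 without basal replicate 1 and 4075 without basal replicate 2.

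Knockout against wildtype under basal conditions asked what differs at rest. Interferon-stimulated genes were lower in the knockout: 21 of 38 passed and fell, 0 rose, with Ifi44 at -1.90 ± 0.082 (log2 ratio, SE, n = 2, limma adjusted p = 0.00011), Oas2 at -1.37 ± 0.085, Oasl2 at -1.32 ± 0.12 and Oas1a at -0.91 ± 0.068. Granulocyte genes were lower too: 11 of 21 fell and 0 rose, with the antimicrobial peptide gene Camp at -1.75 ± 0.11, Ltf (lactoferrin) at -1.35 ± 0.11, and the calprotectin genes S100a8 and S100a9 at -1.17 ± 0.085 and -1.12 ± 0.073. The eosinophil granule gene Epx fell by 1.42 ± 0.18, while the mast cell and basophil genes Cpa3 and Mcpt8 rose by 0.81 ± 0.14 and 0.73 ± 0.13. The largest fall was that of Slfn8, at -3.10 ± 0.16, but its other kept probe gave 0.22. The interferon-induced gene Rtp4 fell by 1.90 ± 0.15.

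The list test put the interferon genes at camera adjusted p = 1.05e-15 and the granulocyte genes at 8.59e-15. With an estimated correlation these were adjusted p = 0.34 and adjusted p = 0.56. Adjusted over the list alone, 26 interferon and 17 granulocyte genes fell. Matrix protease genes fell in 3 of 20 cases, with Fn1 at -1.13 ± 0.21, Mmp14 at -0.71 ± 0.077 and Thbs1 at -0.51 ± 0.091 (adjusted p = 0.0041, and adjusted p = 0.56 with an estimated correlation). The cell cycle list had 1 of 36 genes past the threshold, Rrm2 at -0.61 ± 0.11 (adjusted p = 0.0041, and adjusted p = 0.64 with an estimated correlation), and its mean was 0.0054 without basal replicate 1 and 0.059 with median centring. The unfolded protein response list was higher, with Atf4 at 0.37 ± 0.066 (0.15 by its other kept probe) the only member past the threshold among 18 (adjusted p = 0.031, and adjusted p = 0.56 with an estimated correlation). Lists of MHC class I (mean -0.15, adjusted p = 0.0096), glycolysis (mean -0.13, adjusted p = 0.017) and stromal genes (mean -0.16, adjusted p = 0.026) were lower on balance, with 0 of 14, 0 of 20 and 1 of 16 members past the threshold, and adjusted p = 0.56, 0.56 and 0.61 with an estimated correlation. With median centring the means of the MHC class I and glycolysis lists were 0.17 and 0.20. Il10 was not well above background in either genotype. The log2 ratios of Tnf, Il6 and Il1b were -0.19 ± 0.073, -0.06 ± 0.087 and -0.20 ± 0.072, none past the threshold, and that of Il6 was 0.08 without basal replicate 2.

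The largest rise was that of Ccr6, at 3.91 ± 0.11 (adjusted p = 3.79e-05). Other large rises were those of the desmosome gene Dsc3 (at least 7.24-fold), the syndecan gene Sdc4 (2.61 ± 0.16), Cela2a (at least 5.10-fold), Serpina6 (at least 5.09-fold), Adamtsl2 (2.43 ± 0.078), the keratin genes Krt6b (2.42 ± 0.066) and Krt78 (2.30 ± 0.075), Tpbg (2.36 ± 0.075) and Pou4f2 (at least 4.25-fold). The other kept probe of Krt6b gave a log2 ratio of 0.13. In total 795 genes were higher and 352 lower, and 5 genes passed in both conditions with opposite signs. Median centring gave 3812 higher and 647 lower, and the processed signals gave 428 higher and 330 lower. For Cdk5r1 the call (-0.48 ± 0.094, adjusted p = 0.040) was lost with the processed signals (-0.50, adjusted p = 0.14) and when either basal array was left out. The call was also lost under most other alternatives, with adjusted p up to 0.35, while the log2 ratio stayed between -0.59 (without basal replicate 1) and -0.33 (median centring). On both arrays 136 genes were at least 2-fold higher and 25 at least 2-fold lower, and 7 were 2-fold changed in opposite directions. With the processed signals the 161 genes 2-fold changed the same way became 780.

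Under LPS, Il10, the gene of an anti-inflammatory cytokine, was higher in the knockout by 1.91 ± 0.066 (log2 ratio, SE, n = 2, limma adjusted p = 4.90e-05), at 1.90 and 1.91 on the arrays. Il1b was lower, at -0.75 ± 0.072 (adjusted p = 0.0020; -0.73 with adjusted p = 0.050, not past the threshold, without LPS replicate 1, and -0.11 with adjusted p = 0.44 under median centring), as were Il1a (-0.87 ± 0.096), Il12a (-0.55 ± 0.072) and the chemokine gene Cxcl3 (-1.07 ± 0.089). Tnf was at -0.45 ± 0.073 and Il6 at -0.35 ± 0.087 (adjusted p = 0.012 and 0.049), but with median centring their log2 ratios were 0.04 and 0.27, neither past the threshold. Without LPS replicate 1 or 2 they were of about the same size, at -0.42 and -0.49 for Tnf and -0.31 and -0.38 for Il6, but neither passed (adjusted p = 0.14 and 0.10, and 0.31 and 0.20). Cell cycle genes were lower, 22 of 36 against 1 higher, with Rrm2 at -1.16 ± 0.11, Ccnb1 at -0.96 ± 0.11, Aurka at -0.73 ± 0.086 and Cdk1 at -0.70 ± 0.089. The other kept probes gave -0.30 and -0.17 for Ccnb1 and -0.44 and 0.016 for Cdk1. Granulocyte genes fell again, 14 of 21 with 0 higher, with Ltf at -1.88 ± 0.11, S100a8 at -1.64 ± 0.085, S100a9 at -1.63 ± 0.073 and Camp at -1.53 ± 0.11, beside Prg2 at -1.60 ± 0.16 and Epx at -1.69 ± 0.18.

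The granulocyte list had camera adjusted p = 1.04e-11 and the cell cycle list 6.69e-12, and with an estimated correlation both had adjusted p = 0.53. Adjusted over the list alone, 17 granulocyte and 25 cell cycle genes were lower. Of 20 pro-inflammatory cytokine genes 8 were lower and 3 higher (adjusted p = 0.032, and adjusted p = 0.53 with an estimated correlation), and the call was lost with the processed signals (adjusted p = 0.28) and with median centring (mean 0.086). Glycolysis genes were lower in 5 of 20 cases and higher in 1, Pfkfb3 (0.62), named after its value was seen, with Ldha at -0.67 ± 0.096 and Tpi1 at -0.59 ± 0.090, and -0.22 by the other kept probe of Tpi1 (adjusted p = 0.013, and adjusted p = 0.54 with an estimated correlation), and their mean was 0.16 with median centring. The lists of NRF2 targets (mean -0.18, adjusted p = 0.019), unfolded protein response (mean -0.13, adjusted p = 0.034), phagocytic receptors (mean -0.19, adjusted p = 0.013) and matrix proteases (mean -0.12, adjusted p = 0.032) were also lower, with 3, 6, 7 and 7 members lower and 0, 2, 1 and 1 higher, each with adjusted p = 0.53 with an estimated correlation, and with median centring their means were 0.11, 0.13, 0.11 and 0.075. Dendritic cell markers were the only list past the threshold that was higher, 3 of 20 against 1 lower, with Dpp4 at 1.26 ± 0.12, Irf8 at 0.57 ± 0.096, Kmo at 0.37 ± 0.074 and Itgax at -0.59 ± 0.071 (adjusted p = 0.019, and adjusted p = 0.53 with an estimated correlation). Of the 13 MHC class II genes 4 were higher, Cd74 at 0.59 ± 0.098, H2-Ab1 at 0.51 ± 0.081, H2-Eb1 at 0.51 ± 0.092 and H2-Eb2 at 0.52 ± 0.078, while the list had adjusted p = 0.18. Of 24 alternative activation markers 7 were lower, with Chil3 at -1.32 ± 0.12 and F13a1 at -0.81 ± 0.099, and 3 higher, with Retnla at 1.89 ± 0.21 and Ccl24 at 1.59 ± 0.15 (adjusted p = 0.28).

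Other large falls under LPS were Slfn8 at -4.92 ± 0.16, Csta2, of the stefin family of protease inhibitors, at -3.90 ± 0.16, the xylosyltransferase gene Xylt2 at -1.99 ± 0.095 and the adenosine receptor gene Adora2b at -1.93 ± 0.091. The other kept probes of Slfn8, Xylt2 and Adora2b gave -0.59, -0.52 and -1.14. Other large rises were the phosphatase gene Acp6 (2.59 ± 0.073), Adamtsl2 (2.52 ± 0.078), the muscle gene Csrp3 (2.38 ± 0.25), Krt6b (2.27 ± 0.066, but 0.090 by its other kept probe), Dsc3 (at least 7.96-fold), Zfp647 (at least 5.53-fold) and the meiotic gene Spo11 (at least 5.51-fold). The interferon-induced genes Ifi44 and Xaf1 were at -0.86 ± 0.082 and -0.95 ± 0.076 and Oasl1 at 0.34 ± 0.066, but the other kept probe of Xaf1 gave 6.56 and the mean over both probes 2.81. In total 1690 genes were higher and 1232 lower. Without LPS replicate 1 the count fell from 2922 to 515, and without LPS replicate 2 to 410, and median centring gave 4633 higher and 859 lower. At least 2-fold higher on both arrays were 181 genes, 40 were at least 2-fold lower, and 0 were 2-fold changed in opposite directions. The total of 221 became 1014 with the processed signals and 359 with median centring.

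**Figure D2:**
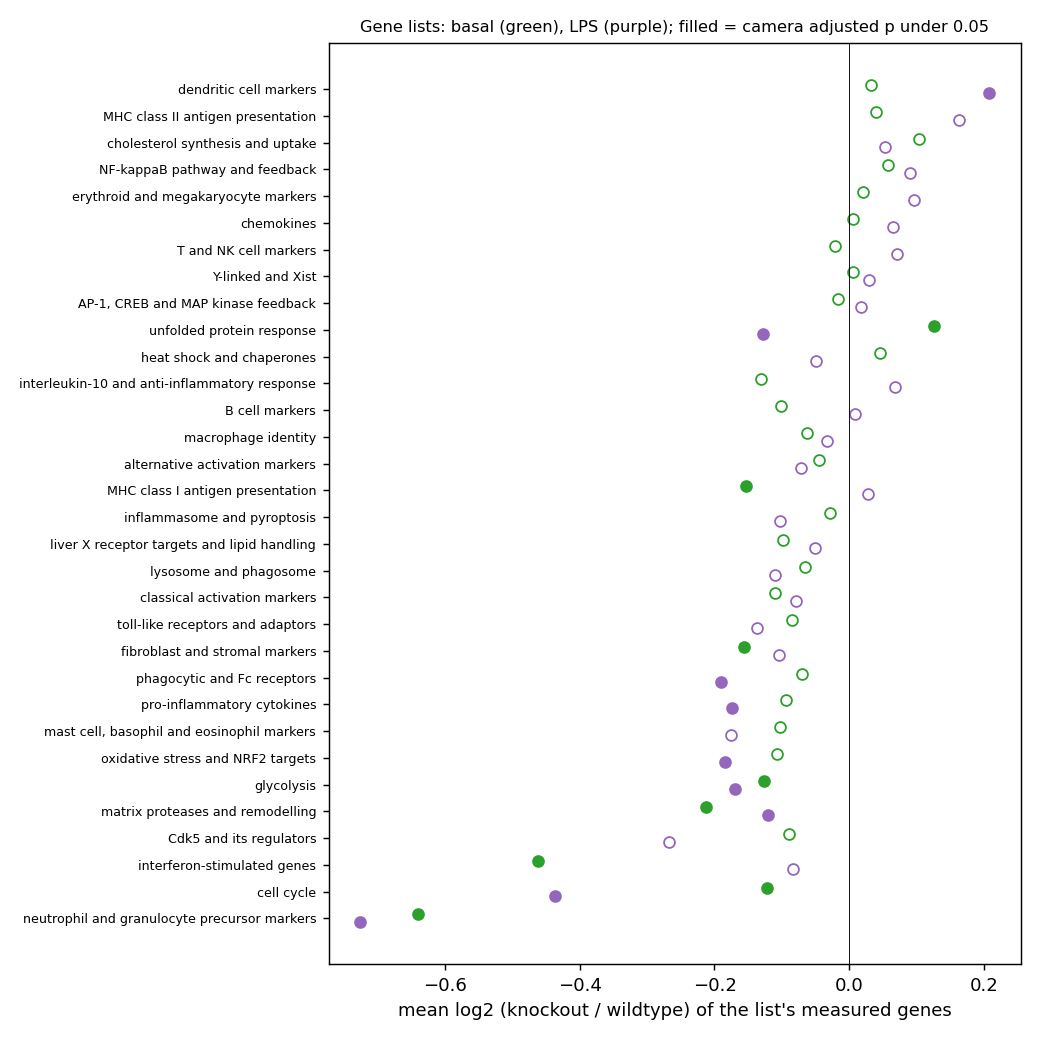
Mean log2 ratio of knockout over wildtype over the measured genes of each list, basal in green and LPS in purple, filled where the camera adjusted p passed. The granulocyte list lies lowest in both conditions, at -0.64 and -0.73, and the interferon list is at -0.46 under basal conditions and -0.08 under LPS.

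Averaged over both conditions, the knockout effect among genes that went the same way on every array was largest downwards for Slfn8 (-4.01 ± 0.11, SE, n = 2 arrays in each condition, limma adjusted p = 8.76e-06; -0.185 by its other kept probe), Camp (-1.64 ± 0.077), Ltf (-1.61 ± 0.077), Spink2 (-1.58 ± 0.089), Epx (-1.56 ± 0.13) and Prg2 (-1.55 ± 0.11). Csta2 averaged -1.94 but did not go the same way on the basal arrays. The heme oxygenase gene Hmox1 was at -1.54 ± 0.30, with a log2 ratio between -2.43 and -0.35 on the arrays, and -0.44 by its other kept probe. Among the largest rises with signal above background in every group were Adamtsl2 (2.48 ± 0.055), the syndecan gene Sdc4 (2.36 ± 0.12) and Krt6b (2.35 ± 0.047, 0.11 by its other kept probe). Il1b was at -0.47 ± 0.051 (adjusted p = 0.0018), and at -0.089 with adjusted p = 0.30 under median centring. In total 2344 genes were higher and 1937 lower. Of the lists past the threshold 8 were lower and 0 higher (6 of the 8 had a mean above 0 with median centring). Of the granulocyte genes 17 of 21 fell (camera adjusted p = 3.49e-12, and adjusted p = 0.56 with an estimated correlation). Tnf was at -0.32 ± 0.051 and Il6 at -0.20 ± 0.061 (adjusted p = 0.0091 and 0.066), and with median centring they were at 0.01 and 0.07. The calls in the separate conditions shared 630 higher and 190 lower genes, where independent lists would share 57 and 18.4, and a dye effect common to all arrays would add to both numbers. Median centring gave 7262 higher and 1677 lower, and the processed signals 1274 higher and 1670 lower.

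The difference of the knockout effect, LPS minus basal, asked where the genotypes respond differently. A constant dye effect cancels in it where the probe has signal in both conditions. Il10 had a difference of 1.90 ± 0.093 (log2, SE, n = 2 arrays in each condition, limma adjusted p = 0.0018), and Acp6 had 2.55 ± 0.10. Spo11 (2.63 ± 0.12) and Ttc36 (2.02 ± 0.11), like Il10, were not well above background in 3, 2 and 2 of the 4 groups, so their sizes rest on dim signals. Where a condition has no signal a dye effect does not show, so it need not cancel for such genes. The Il10 difference thus stays open to dye bias, as its LPS ratio does. Csta2 was at -3.92 ± 0.23, with a basal level that varied between arrays (SD 3.26 in wildtype and 3.67 in knockout, n = 2), Ccr6 at -3.49 ± 0.15 and Cdk5r1 at -1.94 ± 0.13. Under LPS the log2 level of Ccr6 was 6.55 in wildtype and 6.96 in knockout cells. The lowest well-above-background signals of the LPS arrays were 5.76 to 6.145, so the LPS ratio of Ccr6 rests on dim signals. Among interferon-stimulated genes Oasl2 (1.54 ± 0.17), Oas2 (1.14 ± 0.12), Oasl1 (1.05 ± 0.093) and Ifi44 (1.04 ± 0.12) had positive differences, as had Gzmb (1.22 ± 0.15, not well above background in 2 of the 4 groups), while Cxcl3 was at -1.16 ± 0.13. The other kept probe of Pigx (-1.51 ± 0.096) gave -1.33, and that of Arhgap19 (1.87 ± 0.12) gave -0.0064.

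Of the lists, the interferon list had a mean difference of 0.38, with 5 of 38 genes past the threshold, all positive, and 19 positive and 1 negative adjusted over the list alone. The fifth was Oas1a (0.82), named after its value was seen. The list test gave the interferon genes a low p (camera adjusted p = 4.06e-14, and adjusted p = 0.38 with an estimated correlation). The cell cycle list was at -0.32 with 0 of 36 genes past the threshold and 18 lower when adjusted over the list alone (adjusted p = 1.42e-10, and adjusted p = 0.70 with an estimated correlation). The unfolded protein response list was at -0.25 (adjusted p = 1.43e-05, and adjusted p = 0.56 with an estimated correlation). In total 66 genes had a positive and 29 a negative difference. The count of 95 fell to 6 with the processed signals, to 5 without LPS replicate 1, to 4 without LPS replicate 2 and to 58 with the replicate block. Il10 was at 2.17 with the processed signals, with adjusted p = 0.092, and without LPS replicate 1 or 2 the calls of Il10 (1.90 and 1.89, adjusted p = 0.052 and 0.070), Cdk5r1 (-1.81 and -2.07, adjusted p = 0.059 and 0.074) and Csta2 (-3.67 and -4.17, adjusted p = 0.053 and 0.070) were lost at about the same size. Tnf (-0.27 ± 0.10), Il6 (-0.29 ± 0.12) and Il1b (-0.55 ± 0.10) did not pass, and with median centring Tnf and Il6 were at 0.05 and 0.40.

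**Figure D3:**
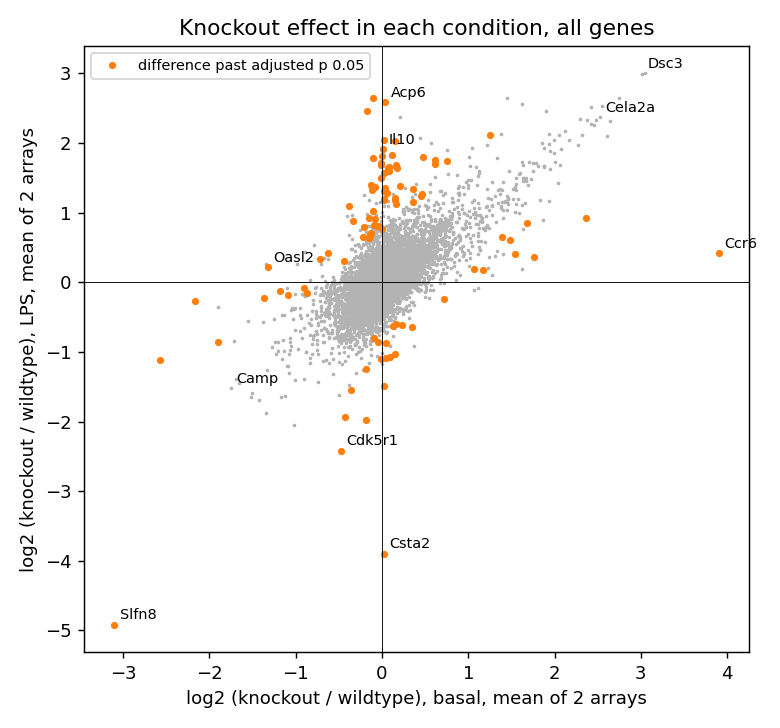
Log2 ratio of knockout over wildtype for every gene, basal on the horizontal and LPS on the vertical axis, each the mean of 2 arrays, with genes whose difference passed in orange. Il10 and Acp6 lie near 0 on the basal axis and at 1.91 and 2.59 under LPS, and Slfn8 is lowest on both axes.

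The strain name, B6.129S4-Cdk5r1tm1Lht/J, places the allele in a C57BL/6 background with sequence of another strain, so genes near Cdk5r1 on chromosome 11 were compared with all other located genes. Within 5 Mb, 8 of 153 genes were lower and 5 higher in the knockout under basal conditions, which was 8.50% against 4.96% past the threshold elsewhere (odds ratio 1.78, 95% interval 0.92 to 3.16, Fisher's exact test, adjusted p = 0.12). Within 10 Mb, 29 of 293 genes passed (9.90% against 4.90%, odds ratio 2.13, 95% interval 1.39 to 3.16, adjusted p = 0.0067). Under LPS the odds ratios were 1.39 and 1.40 (adjusted p = 0.18 and 0.093). In cells of wildtype mice, where the allele is absent, LPS against basal had odds ratios of 1.42 (95% interval 1.02 to 1.99) within 5 Mb and 1.28 (1.01 to 1.62) within 10 Mb, both with adjusted p = 0.093. Both windows hold chemokine genes such as Ccl2 and Ccl5, and 19 of 21 chemokine genes rose with LPS in wildtype cells. The LPS odds ratios are therefore no control for the knockout comparisons. The 8 genes in the wider window with the smallest p averaged over both conditions were Slfn8 (-4.01, but -0.185 by its other kept probe), Msi2 (-0.96), Xaf1 (-0.76, but 5.42 by its other kept probe), Coil (-0.62) and Epx (-1.56), which were lower at the reported probe, and Olfr464 (1.13), Spag7 (0.94) and Olfr399 (1.24), which were higher.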

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

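The test of a smaller granulocyte share was chosen after the result was seen, as were the share of granulocyte genes lower against all genes, the share of other probes that were lower and the condition that the neighbour test look at all knockout comparisons. The knockout effect differed between LPS and basal conditions for 95 genes by the test of the difference itself. The sizes of genes dim in part of the groups, among them Spo11, Ttc36, Il10, Arhgap19, Olfr1303, Ntn5 and Serpina3k, rest on dim signals. A dye effect need not cancel in the differences of these genes, since it does not show without signal. Positive differences (log2, LPS minus basal) were 2.63 for Spo11, 2.55 for Acp6, 2.02 for Ttc36, 1.90 for Il10, 1.87 for Arhgap19, 1.82 for Olfr1303, 1.73 for Ntn5, 1.71 for Serpina3k, 1.56 for Il17rd and 1.54 for Oasl2. Negative differences were -3.92 for Csta2, -3.49 for Ccr6, -1.94 for Cdk5r1, -1.82 for Slfn8, -1.80 for Xylt2, -1.51 for Pigx, -1.50 for Adora2b, -1.44 for Tpbg, -1.41 for Sult1d1 and -1.19 for Tns1. Among the lists, the mean difference was 0.20 for the interleukin-10 and anti-inflammatory list, 0.38 for interferon-stimulated genes, 0.18 for MHC class I, 0.18 for dendritic cell markers, -0.32 for the cell cycle and -0.25 for the unfolded protein response. Their members past the threshold were 1 of 24, 5 of 38, 0 of 14, 0 of 20, 0 of 36 and 0 of 18. With an estimated correlation the 6 lists had adjusted p = 0.70, 0.38, 0.70, 0.70, 0.70 and 0.56. The other kept probes gave -0.46 for Xylt2, -0.81 for Slfn8, -0.87 for Adora2b, -0.32 for Tns1 and -0.0064 for Arhgap19.

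Among named genes at least 2-fold higher in the knockout averaged over both conditions there were 107, and in 41 of them the wildtype channel was not well above background on any array. Of the 24 genes with another kept probe, 20.8% had it past the threshold and higher (exact 95% interval 7.13% to 42.2%). A gene counted here if any of its other kept probes did so. Among all other kept probes, counted singly, the share was 6.90%. These values argue against a higher transcript level over the whole gene for most of these 24 genes, as far as a dimmer probe would show it. A share by gene and a share by probe are not alike, so the interval cannot be set closely against 6.90%. Such a rise stays open for some of the genes. The median ratio of the other probes to the reported probe was 0.034 (95% bootstrap interval 0.012 to 0.064), the outcome set beforehand for a dye effect of single probes. Part of a low ratio is built in, since the reported probe was the brightest and was picked for its size. Probes that bind different transcripts stay open too. For the genes at least 2-fold lower, 10 of 33 had another kept probe, and 80.0% of these had it past the threshold and lower. The exact 95% interval was 44.4% to 97.5%, against 6.61% of all other kept probes counted singly. Of the 10 genes only Serinc3 had 2 other probes. For most of these 10 genes the values argue against a dye effect of the reported probe alone. The ratio there was 0.33 (0.17 to 0.70), so a dye effect that adds to the size at single probes cannot be told apart from the choice of the largest changes.

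For the genes near Cdk5r1, the odds ratio averaged over both conditions within 10 Mb was 1.29 (95% interval 0.97 to 1.70). Sequence kept from the donor strain and a dye effect spread over the genome cannot be told apart by it, since the interval includes 1 while the basal value of 2.13 lies above 1. The same window had an odds ratio of 1.28 for LPS against basal in wildtype cells, where sequence of the donor strain cannot act. It holds chemokine genes such as Ccl2 and Ccl5, and most chemokine genes rose with LPS. That odds ratio therefore speaks neither for nor against donor sequence in the knockout comparisons. The other kept probe of Slfn8 had a log2 ratio of -0.185 against -4.01 for the reported probe, and whether a strain variant lies under a probe was not tested.

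Granulocyte markers were lower in both conditions, and 81.0% of the 21 measured genes passed and were lower averaged over both, with 0% higher. The share of lower genes had an exact 95% interval of 58.1% to 94.6%, against 8.22% of all genes. This comparison was chosen after the list was seen to lie lowest in both conditions. The interval makes no allowance for that choice and takes the genes as independent. Dye effects of single probes, unrelated to what the genes do, were weighed as the whole cause. The share argues against them only as far as the choice of list allows. The other kept probes of Camp and Ly6c1, the only 2 of the lower genes with another, had a ratio of 0.878, above the bound of 0.75 set beforehand against a dye effect, but resampling 2 genes gives no interval, so whether a dye effect adds to the sizes stays open. A smaller share of granulocytes in the knockout cultures and lower expression per cell cannot be told apart, since the share of lower markers is the pattern itself.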

How the results depend on the processing

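The crossed pairing of replicate numbers was chosen after seeing the data. A fit by slide or scan was not run, since there was 1 of each, and the value table, holding ratios only, gave no value for LPS against basal. Of 3304 gene values under alternatives 2993 kept direction and side of the threshold, 295 lost the call, 4 gained it and 12 turned sign; of 607 list values 440 kept both, 159 lost the call and 8 turned in the direction of the list test. Counts of genes (knockout against wildtype basal, LPS and averaged, then the difference; 1147, 2922, 4281 and 95) were 758, 1777, 2944 and 6 with the processed signals (56.5%, 49.6%, 43.3% and 83.3% higher, against 69.3%, 57.8%, 54.8% and 69.5%), 4459, 5492, 8939 and 228 with median centring (85.5%, 84.4%, 81.2% and 75.4% higher) and 730, 1725, 2796 and 8 with the value table (60.3%, 54.3%, 49.3% and 87.5% higher). Requiring all channels above background gave 704 (basal) and 19 (difference), and trend and robust eBayes gave 705 and 34. With the replicate block, by numbers that share only a label (correlation of deviations -0.161), counts were 927, 2160, 3173 and 58, and 8210 and 8108 for LPS in wildtype and knockout cells; crossed pairing gave 1842, 4395, 5868 and 367. Leaving out 1 array gave 708 to 775, 410 to 3146, 1713 to 2990 and 4 to 198, and 5194 to 8849 and 4075 to 9615 for LPS in wildtype and knockout cells, where scaling to the 75th percentile gave 15688 and 14987 (73.2% and 72.2% higher, against 43.7% and 45.5%); a lone array is assumed to vary like the others. Genes at least 2-fold changed on both arrays were 780 basal and 1014 LPS with the processed signals and 359 LPS with median centring. Lists past the threshold (8, 9, 8, 6, then 17 and 16 for LPS) were 0 in each with an estimated correlation, 1, 0, 2, 0, 23 and 21 with fry, 3, 2, 4 and 3 with the processed signals, 13 basal with median centring, and 6 to 9, 3 to 10, 5 to 11 and 3 to 9 without 1 array. Values that turned sign under median centring were Il10 basal -0.12, Tnf and Il6 under LPS 0.039 and 0.27, averaged 0.012 and 0.075, and in the difference 0.052 and 0.40; and the lists MHC class I basal 0.17, glycolysis basal 0.20, LPS 0.16 and averaged 0.18, NRF2 targets LPS 0.11, unfolded protein response LPS 0.13 and phagocytic receptors averaged 0.17. The means alone turned, with the direction against other genes kept, for the cell cycle basal (0.059), cytokines (0.086), phagocytic receptors (0.11) and matrix proteases (0.075) under LPS, and cytokines (0.010), interferon-stimulated genes (0.012), toll-like receptors (0.052) and matrix proteases (0.011) averaged. Xaf1 under LPS turned to 2.81 with the mean over probes. Without 1 array, Il10 basal ran from -0.0011 to 0.026, Il6 basal from -0.20 to 0.081, the Cdk5 difference from -0.055 to 0.041, Cdk5r1 for LPS in knockout cells from -0.39 to 0.44 and the basal cell cycle list from -0.25 to 0.0054. The neighbour odds ratio basal was 2.13 at 10 Mb. With the processed signals the Cdk5r1 log2 ratio was -2.62 under LPS, and by its other probe -0.68 basal and -2.63 LPS. The cause was not tested.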

Other observations

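In wildtype cells LPS also raised genes that the fixed lists assign to other cells. Hdc, the histidine decarboxylase gene, rose by 6.67 ± 0.19 (log2, SE, n = 2, limma adjusted p = 0.00028), and by 6.69 ± 0.19 in knockout cells. The siderophore-binding gene Lcn2 rose by 4.19 ± 0.32 in wildtype cells, where 16 of 21 granulocyte genes rose and 1 fell. MHC class I genes rose in 13 of 14 cases, with their activator Nlrc5 at 3.35 ± 0.095, and 1.35 by its other kept probe. Cholesterol synthesis genes fell in 11 of 20 cases and rose in 1, with Dhcr7 at -2.36 ± 0.14, and the growth factor receptor gene Csf1r fell by 1.98 ± 0.12.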
